A study of Mus musculus with 8 samples.

How the data were processed

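Total RNA from the hearts of 4 satiated and 4 fasted mice was labelled with Cy3 and hybridised to Agilent whole mouse genome arrays, 1 array and 1 colour per mouse, per the labels. Replicates are separate mice only as far as the labels number separate samples, and the p-values measure the spread between these samples. The deposited scanner tables hold spot intensities on a linear scale, from which Agilent Feature Extraction had subtracted the background on each array, without normalization between arrays, per the file headers. The headers give version 10.5.1.1 of the extraction software for slide 1 and 10.7.3.1 for slide 2, while the submitters' processing notes name version 9.1. Each slide was scanned on its own, so slide, scan and software version could not be told apart from one another, but each slide held 2 hearts of each group. The main comparison held no term for the slide, so its standard errors and p-values also take in differences between the 2 slides. An alternative fit with the slide as a block takes these differences out.

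The deposited table of the whole series holds linear ratios, and how the authors made them is not given in the sources used here. All 41266 of its probes were found in the scanner tables. Set against the scanner values, 99.4% of its probes differed from them by 1 factor per array (within 0.01 on the log2 scale) after a constant per probe was allowed for. The median over the 8 arrays was 1 (within 0.001) for 29172 probes and lower for 12094, the lowest being 0.492, and the column medians were 0.876, 0.901, 0.954 and 0.980 for satiated replicates 1 to 4 and 0.887, 0.860, 1.02 and 0.960 for fasted replicates 1 to 4. The scale is thus linear and the direction that of the intensities, whereas the divisor used for dim probes and the origin of the array factors stay unknown. These ratios served as an alternative source of values.

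From the processed intensities, log2 values were taken and the 75th percentile of each array was subtracted. Of 45018 spots per array 1639 were controls and were left out, as were spots marked as outliers by the extraction software. Spots of the same probe were averaged, and probes well above background on at least 4 of the 8 arrays were kept, 26480 of 41174. Probe accessions were matched to the RefSeq gene table of assembly GRCm38.p6, used for names only, since the array's own annotation is of another build. No coordinates are given for that reason. A symbol was found for 26690 probes (64.8%), covering 18217 genes, none had several, and 14484 stayed unnamed here. Each symbol was represented by its brightest kept probe over all 8 arrays, which left 20203 genes and unnamed probes, 13816 of them with a symbol. Among 6277 other kept probes of the same genes, 720 were called together with the representative probe, and 36, of 35 genes, were called in the opposite direction, Psmd12 and Pes1 among those genes.

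The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 with the package data.table, version 1.17.8, two-sided, with Benjamini-Hochberg adjustment, at an adjusted p under 0.05 and, for a second count, a fold change of at least 2. Figures were drawn with matplotlib 3.10.9. For a gene not well above background on any array of a group, the fold is a bound: the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the gene's own value and the lowest value well above background on that array. The 46 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over all 46, and each had at least 5 measured members. Members were counted over all genes tested and adjusted over the list alone. Genes named in the text were the 10 largest increases and 10 largest decreases with non-overlapping groups and an official-style symbol and, for each list, up to 4 called members with the smallest p, or the single smallest where none was called. The comparison of the groups, the 46 lists and their tests, this rule and all alternatives but 1 were fixed before the data were examined, whereas some tests of explanations and the lists of marker genes they use were written afterwards.

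The comparison was tested on simulated data with 200 changed genes among 20172. It recovered 4% of the 50 genes changed by 0.5 on the log2 scale, 32% of those changed by 1, 80% of those changed by 2 and 88% of those changed by 3, and 6 of its 108 calls were unchanged genes. Far fewer genes changed there than the 4073 of 20203 called in the data, which makes the adjustment stricter. Noise was also drawn independently for each gene, so these shares do not give the recovery in the real comparison. The negative control spots had a median signal of 28.5 to 30 on the arrays of slide 1 and of 136 to 150 on those of slide 2, and the lowest values well above background were correspondingly higher on slide 2.

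Same-numbered hearts of both groups deviated together from their group means, with correlations across genes of 0.331 to 0.493 in the 4 pairs. Differently numbered hearts on the same slide did so to the same degree (0.291 to 0.522), and hearts on different slides deviated in opposite directions (-0.531 to -0.284), so that the pairing comes from the shared slide. The replicate number was used as a block in an alternative fit.

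Alternatives were normexp background correction with an offset of 50, quantile normalization, both together, median centring, no filter on dim probes, a filter asking for all 8 arrays, the mean of a gene's probes, every probe on its own, the deposited ratios, the slide as a block, each slide alone, the replicate number as a block, array weights, a variance prior with a trend, each array left out in turn, an adjusted p under 0.01, an estimated correlation in camera, and fry. Normexp had been planned on mean spot intensities and was run on the median spot and background intensities, which the tables used here hold. The slide block without the array of fasted replicate 3 was added after the data were seen.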

Results

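Messenger RNA was measured in whole hearts of 8 male C57BL/6J mice, 9 weeks old, with 1 one-colour Agilent whole mouse genome array per mouse. C57BL/6J is a standard inbred laboratory strain. Hearts came from 4 satiated mice and from 4 mice deprived of food, with free access to water, for 2 days. The comparison of these 2 groups asks which transcripts of the heart differ after a 2-day fast. The arrays lay on 2 slides of 4 arrays, and each slide held 2 satiated and 2 fasted hearts: replicates 1 and 2 of both groups on slide 1, replicates 3 and 4 on slide 2. Of the 41174 non-control probes, 66.7% to 68.9% were well above background on the arrays of slide 1 and 54.4% to 55.6% on those of slide 2. No spot was saturated. The number of arrays, 4 per group, limits the precision of every value.

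Replicate hearts of a group on the same slide correlated across probes at r = 0.979 to 0.992, against 0.956 to 0.976 for a satiated and a fasted heart on the same slide. Probes are not independent replicates, so these correlations describe the arrays without a test. The first principal component, with 43.7% of the variance, parted the fasted from the satiated hearts, and the second component, with 29.4%, parted the slides. The array of fasted replicate 3 had the lowest mean correlation with its own group, 0.974, and lay at 44.6 on the third component, where fasted replicate 4 lay at -40.5.

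**Figure D1:**
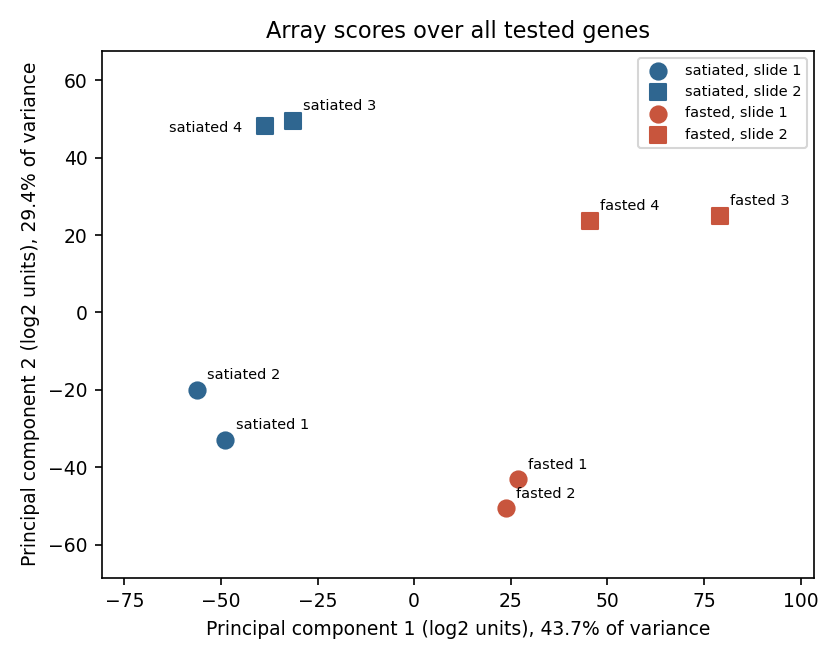
Scores of the 8 arrays on the first and second principal components (both axes in log2 units) over all tested genes, with colour for the group and symbol shape for the slide. Fasted arrays lie between 23.7 and 79.2 on the first component and satiated arrays between -56.3 and -31.5.

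After 2 days without food, lists of PPAR alpha and FoxO target genes, glucocorticoid-induced genes and fetal and hypertrophy-associated genes were higher in the hearts, and lists of glycolysis, cholesterol synthesis, ion channel, collagen and cell cycle genes lower, in a test with a preset correlation between genes; none of these calls held when the correlation was estimated from the data. Among the clearest single changes, Acot1, a cytosolic acyl-CoA thioesterase, rose 7.30-fold (log2 fold change 2.87 ± 0.22, SE, 4 hearts per group), Cdkn1a, the cell cycle inhibitor p21, 9.90-fold (3.31 ± 0.17) and Myh7, the slow beta isoform of myosin heavy chain, 8.96-fold (3.16 ± 0.47). Kcne1, a regulatory subunit of the slow delayed rectifier potassium channel, fell 7.36-fold (-2.88 ± 0.20) and Col15a1, a basement membrane collagen, 4.25-fold (-2.09 ± 0.21). In all, 4073 of 20203 tested genes and unnamed probes changed at a Benjamini-Hochberg adjusted p under 0.05 in limma, 1983 higher and 2090 lower in the fasted hearts, and 1490 of them changed at least 2-fold, 748 higher and 742 lower. Of the 4073, 3064 carried a gene symbol (1459 higher, 1605 lower). The values of the 4 fasted hearts did not overlap those of the 4 satiated hearts for 3935 of the 4073, and for 27.6% of all tested genes and probes, where chance gives 2.86%.

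With the slide as a block 7177 passed, among them all 4073, and 1645 at least 2-fold. Slide 1 alone gave 1883, of which 98.8% changed in the same direction on slide 2, and slide 2 alone gave 1, the unnamed probe A_52_P639461 (-7.04 ± 0.19 on that slide), with 5333 at an unadjusted p under 0.05. The count was 2520 without satiated replicate 2, 2495 without satiated replicate 4, 3690 without fasted replicate 3 and 6486 with the replicate number as a block. It was 2225 of 32701 when dim probes were kept. With normexp background correction, 778 genes passed at 2-fold.

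Of 46 gene lists written before the data were examined, 21 were called by camera with a preset correlation between genes of 0.01 (adjusted p under 0.05), 13 upward and 8 downward, and none of the 21 calls held with a correlation estimated for each list, where the adjusted p ranged from 0.347 to 0.754. Dividing the arrays otherwise also gave calls: satiated and fasted replicates 1 and 3 against replicates 2 and 4 called 17 lists with 0 changed genes. A list call with the preset correlation thus does not by itself set fasting apart from other differences between arrays. The lists held 909 measured genes, of which 258 changed. Values after gene names below are log2 fold changes, fasted minus satiated, ± SE (n = 4 and 4).

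**Figure D2:**
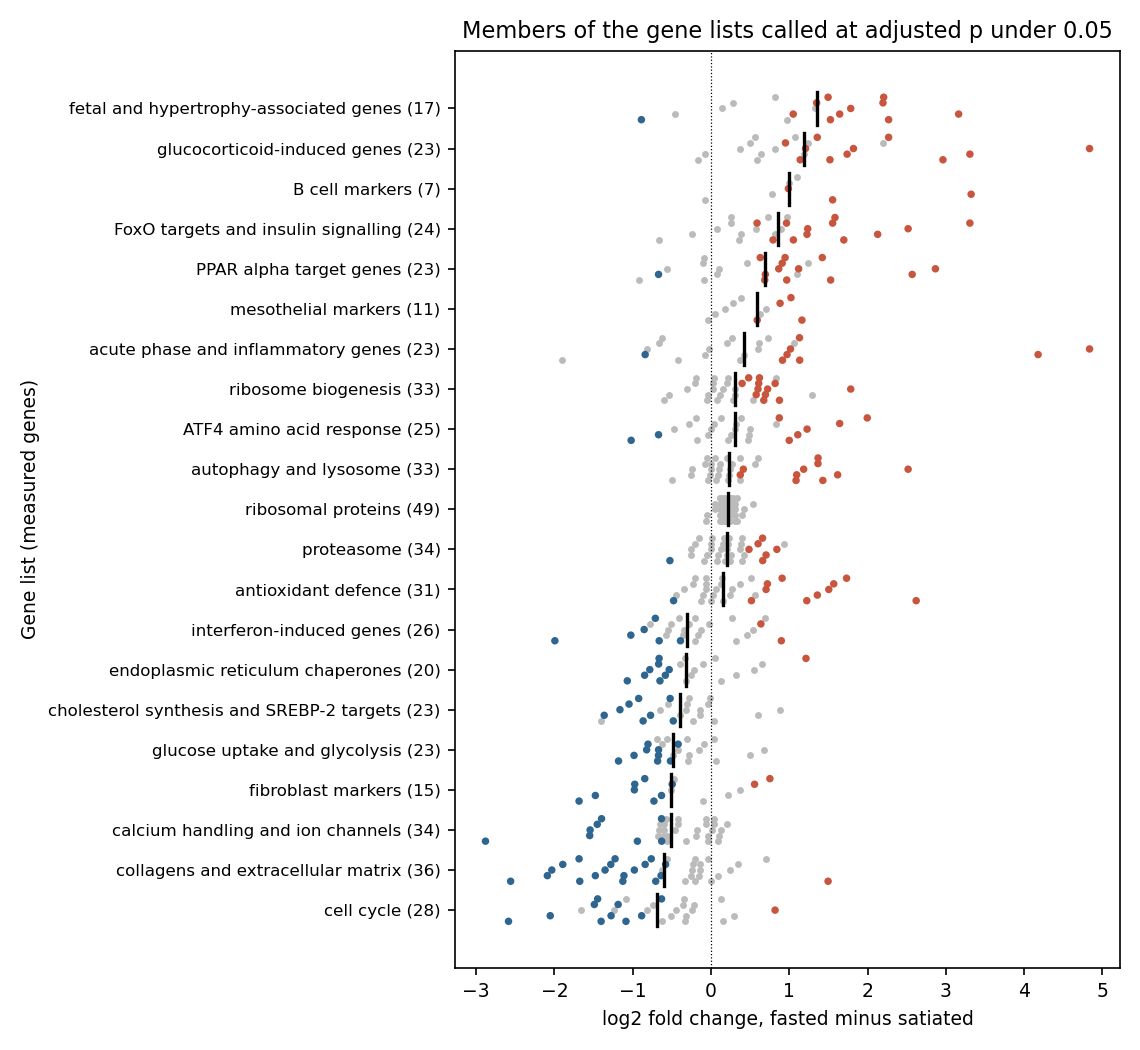
Log2 fold change (fasted minus satiated, horizontal axis) of each measured member of the 21 called gene lists (vertical axis, number of measured genes in parentheses), with genes that rose in red, genes that fell in blue, genes that did not pass in grey and the list's median as a black bar. Medians run from -0.68 for cell cycle genes to 1.35 for fetal and hypertrophy-associated genes.

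Targets of PPAR alpha, the nuclear receptor that drives fatty acid use in fasting, were higher in the fasted hearts. Of 23 measured targets 12 rose, 1 fell and 10 did not pass; 13 rose and 1 fell when adjusted over the list alone. Besides Acot1, the lipid droplet protein Plin2 rose (1.42 ± 0.19). The list's median change was 0.70, with 0.80 on slide 1 and 0.76 on slide 2 (adjusted p = 0.000373, and adjusted p = 0.379 with an estimated correlation). Mitochondrial beta-oxidation genes were not called as a list (adjusted p = 0.268, median 0.04). Of 21 measured, Eci2 (0.42 ± 0.10) and Acadl (0.39 ± 0.10) rose over all genes and none passed when adjusted over the list alone. The calls of Eci2 and Acadl were each lost without any of 6 arrays, with adjusted p of 0.0506 to 0.0737 and of 0.0618 to 0.0875. Eci2 kept its call without satiated replicate 1 or fasted replicate 3, and Acadl without fasted replicate 2 or 3. With the slide as a block in limma 5 of the 21 rose, Eci2 (adjusted p = 0.00771) and Acadl (adjusted p = 0.0104) among them. The list was again not called by camera in that fit (adjusted p = 0.142).

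Genes of fatty acid uptake and triglyceride handling were not called as a list (adjusted p = 0.0655, median 0.35), with 5 of 28 rising and 2 falling over all genes and 7 rising and 2 falling when adjusted over the list alone. Pnpla2, the adipose triglyceride lipase, rose (1.44 ± 0.14) while G0s2, its inhibitor, fell (-1.61 ± 0.19), and the fatty acid transporter Slc27a1 rose (1.40 ± 0.17). The list passed without fasted replicate 2 (adjusted p = 0.0344) and without satiated replicate 4 (adjusted p = 0.0174). Of 7 ketone body genes 1 rose and 1 fell, namely Oxct1, which starts the use of ketone bodies outside the liver (-1.05 ± 0.12), the same 2 when adjusted over the list alone (list adjusted p = 0.912). Among 17 genes of de novo fatty acid synthesis 2 rose, 1 when adjusted over the list alone (list adjusted p = 0.929), led by Acacb, the acetyl-CoA carboxylase of the outer mitochondrial membrane (0.73 ± 0.10). Cholesterol synthesis and other SREBP-2 target genes were lower: 8 of 23 fell and none rose over all genes, and 10 fell when adjusted over the list alone. Cyp51 (-1.36 ± 0.16), Idi1 (-0.87 ± 0.13) and Dhcr7 (-1.05 ± 0.19), all enzymes of the sterol pathway, were among them. The median of that list was -0.39, with -0.28 on slide 1 and -0.52 on slide 2 (adjusted p = 0.00048, and adjusted p = 0.347 with an estimated correlation). Dhcr7 did not pass as the mean of its probes (-0.84, adjusted p = 0.0631).

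Glucose uptake and glycolysis genes were lower in the fasted hearts: 9 of 23 fell and none rose, over all genes and when adjusted over the list alone. Hk2, the insulin-responsive hexokinase of muscle, fell (-1.18 ± 0.14), as did the muscle isoforms of phosphofructokinase and phosphoglycerate mutase, Pfkm (-0.67 ± 0.12) and Pgam2 (-0.68 ± 0.13). The median was -0.48, with -0.54 on slide 1 and -0.39 on slide 2 (adjusted p = 0.00048, and adjusted p = 0.347 with an estimated correlation). Among 11 genes of pyruvate dehydrogenase control, 1 rose over all genes, and 1 rose and 3 fell when adjusted over the list alone (list adjusted p = 0.421). The gene that rose was Pdk4, the kinase that shuts off pyruvate dehydrogenase (1.53 ± 0.43, adjusted p = 0.0377), and its call was lost without any array other than those of satiated replicates 3 and 4 (adjusted p = 0.0526 to 0.0875). Of 17 glycogen genes 3 fell, also when adjusted over the list alone (list adjusted p = 0.53).

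Few genes of oxidative metabolism in mitochondria passed the test. Of 50 measured respiratory chain genes, 0 passed over all genes or when adjusted over the list alone by limma, and 4 had an unadjusted p under 0.05 (median -0.08, list adjusted p = 0.0655). The member with the smallest p, Atp5g1, a subunit of ATP synthase, had a value of -0.35 ± 0.11 (adjusted p = 0.0561). With the slide as a block 10 of the 50 fell and the list was called (adjusted p = 0.0243). Its median was -0.17 on slide 1 and -0.03 on slide 2, and without fasted replicate 3 it was -0.19 (adjusted p = 0.000333). In all, 15 of 27 alternatives called the list, all downward, among them normexp (adjusted p = 0.00267), quantile normalization (adjusted p = 0.000687), array weights (adjusted p = 0.000403) and slide 1 alone (adjusted p = 0.00144), while an estimated correlation (adjusted p = 0.86) and fry (adjusted p = 0.336) did not. Of 17 citric acid cycle genes 1 fell, and none when adjusted over the list alone: Sdhd, a membrane anchor of succinate dehydrogenase (-0.35 ± 0.10, adjusted p = 0.0462), whose call was lost without any 1 of the 8 arrays (adjusted p = 0.0511 to 0.124). With the slide as a block in limma 1 of the 17 rose and 4 fell, Sdhd (adjusted p = 0.0114) among those that fell. The list was not called by camera (adjusted p = 0.163, and 0.0729 with that block) but passed without fasted replicate 3 (adjusted p = 0.00962).

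Glucocorticoid-induced genes showed the smallest p of the 46 lists in camera with the preset correlation; with an estimated correlation, and in fry, calcium handling and ion channel genes did. Of 23 measured 11 rose and none fell over all genes, and 14 rose when adjusted over the list alone. They included Cdkn1a and the metallothioneins Mt1 (2.27 ± 0.24) and Mt2 (2.96 ± 0.31), which bind zinc and copper. The median was 1.18, with 1.1 on slide 1 and 1.18 on slide 2 (adjusted p = 3.49e-08, and adjusted p = 0.347 with an estimated correlation). FoxO targets and insulin signalling genes were higher too, with 12 of 24 rising and none falling over all genes, and 15 rising and 1 falling when adjusted over the list alone. Fbxo31, a substrate receptor of a ubiquitin ligase, rose (2.13 ± 0.16), as did Bnip3, a mitochondrial receptor for autophagy (2.52 ± 0.25), and Ccng2, an atypical cyclin (1.05 ± 0.13). Their median was 0.86, with 0.76 on slide 1 and 0.94 on slide 2 (adjusted p = 1.25e-07, and adjusted p = 0.347 with an estimated correlation).

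Both systems of protein breakdown had members that rose. Among 33 autophagy and lysosome genes 10 rose and none fell over all genes, and 12 rose when adjusted over the list alone. The lysosomal protease Ctsl (1.37 ± 0.20) and Uvrag (1.37 ± 0.21), which acts in the maturation of autophagosomes, were examples. The median was 0.23, with 0.17 on slide 1 and 0.33 on slide 2 (adjusted p = 0.000928, and adjusted p = 0.455 with an estimated correlation). Of 34 proteasome subunit genes 6 rose and 1 fell, the same numbers when adjusted over the list alone, with Psmd7 (0.66 ± 0.12) and Psmd11 (0.84 ± 0.16) of the regulatory particle among those that rose. The proteasome median was 0.21, with 0.14 on slide 1 and 0.29 on slide 2 (adjusted p = 0.0123, and adjusted p = 0.754 with an estimated correlation). That call was lost without fasted replicate 3 (median 0.15, adjusted p = 0.0683), with array weights (adjusted p = 0.0603), with normexp background correction (adjusted p = 0.0614) and on slide 1 alone (adjusted p = 0.093).

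Ribosome biogenesis genes were higher: 12 of 33 rose and none fell over all genes, and 13 rose and 1 fell when adjusted over the list alone. Myc, a transcription factor that drives ribosome production, rose (1.79 ± 0.28), as did Nhp2 (0.88 ± 0.14), a protein of the RNA-modifying box H/ACA particles, and the RNA helicase Ddx56 (0.72 ± 0.11). The median was 0.31, with 0.29 on slide 1 and 0.33 on slide 2 (adjusted p = 0.000938, and adjusted p = 0.455 with an estimated correlation). Of 49 ribosomal protein genes, 0 passed over all genes or when adjusted over the list alone by limma, 7 had an unadjusted p under 0.05, and Rpl30, with the smallest p, had a value of 0.54 ± 0.17 (adjusted p = 0.0526). The list was nonetheless called upward, with a median of 0.22, 0.14 on slide 1 and 0.27 on slide 2 (adjusted p = 0.000311, and adjusted p = 0.626 with an estimated correlation), and 13 members rose with the slide as a block.

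Stress response lists moved in different directions. Of 25 ATF4 amino acid response genes 6 rose and 2 fell over all genes, and 8 rose and 2 fell when adjusted over the list alone. Ppp1r15a, the stress-induced phosphatase subunit GADD34 (2 ± 0.33), Trib3, a pseudokinase (1 ± 0.15), and Slc3a2, the heavy chain of several amino acid transporters (0.87 ± 0.11), rose, and Psph, which makes serine, fell (-1.02 ± 0.16). The median was 0.30, with 0.20 on slide 1 and 0.33 on slide 2 (adjusted p = 0.031, and adjusted p = 0.347 with an estimated correlation). That call was lost without satiated replicate 2 (adjusted p = 0.0528), fasted replicate 3 (0.0683) or fasted replicate 4 (0.0516), on slide 1 alone (0.0519), with array weights (0.0603), with normexp background correction (0.0612) and with every probe on its own (0.0988). Of 31 antioxidant genes 10 rose and 1 fell, the same numbers when adjusted over the list alone, with Hmox1, the inducible haem oxygenase (2.62 ± 0.23), Cat, catalase (1.22 ± 0.11), and Mgst1, a microsomal glutathione transferase (1.73 ± 0.20), among those that rose. Their median was 0.15, with 0.19 on slide 1 and 0.15 on slide 2 (adjusted p = 0.0132, and adjusted p = 0.455 with an estimated correlation).

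Chaperones of the endoplasmic reticulum were lower: 1 of 20 rose and 8 fell over all genes, and 2 rose and 9 fell when adjusted over the list alone. Sdf2l1 (-1.07 ± 0.13) and the calcium-binding lectin Calr (-0.85 ± 0.12) fell and Dnajc3, the co-chaperone P58IPK, rose (1.21 ± 0.19). The median was -0.32, with -0.26 on slide 1 and -0.35 on slide 2 (adjusted p = 0.0145, and adjusted p = 0.455 with an estimated correlation). That call was lost on slide 1 (adjusted p = 0.0585) and slide 2 alone (0.0562), with the replicate number as a block (0.0938) and with every probe on its own (0.0878). Heat shock proteins were not called as a list (adjusted p = 0.119, median -0.29), with 3 of 24 rising and 7 falling over all genes, and 4 rising and 9 falling when adjusted over the list alone. Among them, Hsph1, a large cytosolic chaperone (-1.16 ± 0.14), and Hspd1, the mitochondrial chaperonin (-0.81 ± 0.14), fell. The list passed without satiated replicate 1 (adjusted p = 0.0448) and without fasted replicate 3 (adjusted p = 0.0434).

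**Figure D3:**
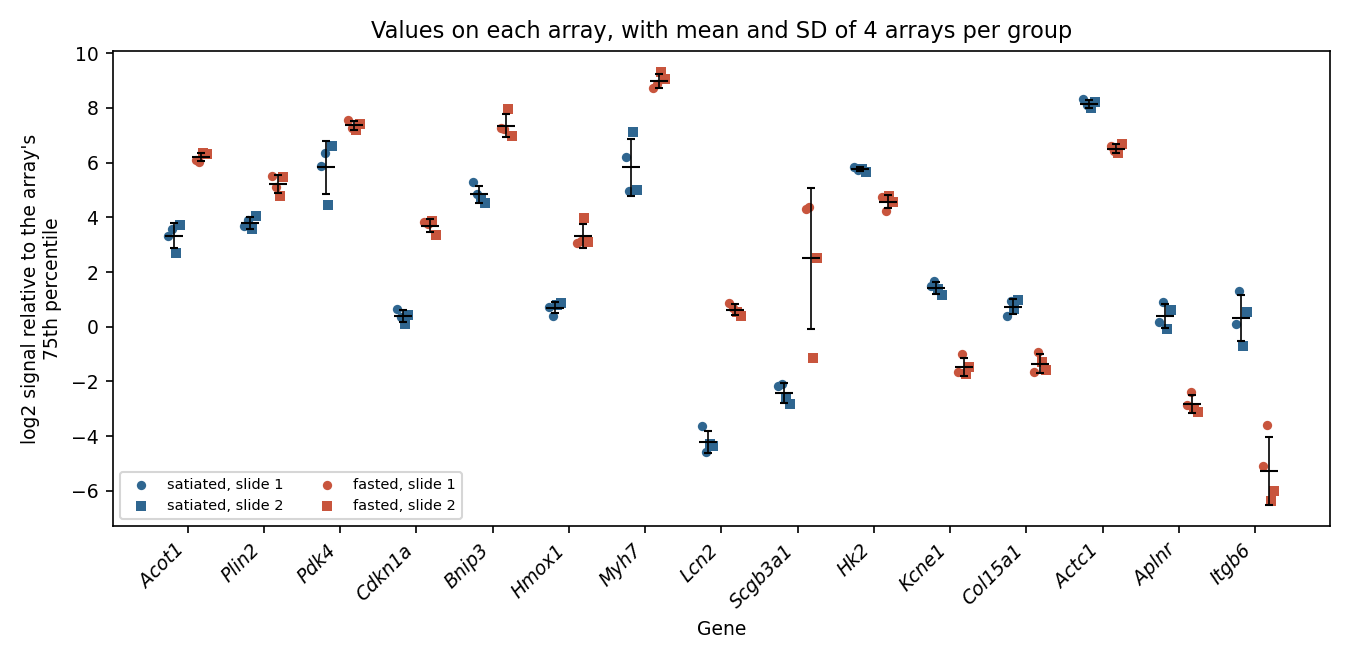
Log2 signal relative to each array's 75th percentile (vertical axis) for 15 of the named genes (horizontal axis) on each of the 8 arrays, with the mean and SD of each group in black. The 4 fasted hearts lie above the 4 satiated hearts from Acot1 to Scgb3a1 and below them from Hk2 to Itgb6, and Scgb3a1 spreads from -1.15 to 4.36 among the fasted hearts.

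Fetal and hypertrophy-associated genes were higher. Of 17 measured 10 rose and 1 fell over all genes and when adjusted over the list alone. Apart from Myh7 and Mt1, Timp1, an inhibitor of matrix metalloproteinases, rose (1.5 ± 0.20), and Xirp2, an actin-binding protein of the intercalated disc, fell (-0.89 ± 0.12). The median was 1.35, with 1.15 on slide 1 and 1.58 on slide 2 (adjusted p = 0.000114, and adjusted p = 0.347 with an estimated correlation). Sarcomere genes were not called as a list (adjusted p = 0.401, median -0.08): 5 of 24 fell and none rose, also when adjusted over the list alone, led by Actc1, the cardiac alpha-actin (-1.64 ± 0.13), and Nebl, a thin filament protein (-0.97 ± 0.21). Calcium handling and ion channel genes were lower, with 8 of 34 falling and none rising over all genes, and 11 falling when adjusted over the list alone. Besides Kcne1, Kcnd2, a subunit of the transient outward potassium channel, fell (-1.54 ± 0.12), as did Gja5, the gap junction protein connexin 40 (-1.55 ± 0.30). The median was -0.51, with -0.35 on slide 1 and -0.40 on slide 2 (adjusted p = 0.00048, and adjusted p = 0.347 with an estimated correlation). Adrenergic, thyroid and natriuretic signalling genes were not called as a list (adjusted p = 0.912): 2 of 24 rose and 4 fell over all genes, and 3 rose and 4 fell when adjusted over the list alone. Adrb1, the main beta-adrenergic receptor of heart muscle, fell (-1.73 ± 0.20), as did the retinoid receptor Rxrg (-1.48 ± 0.23), and Grk5, a kinase that desensitises such receptors, rose (0.85 ± 0.17).

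Extracellular matrix genes were lower in the fasted hearts, with 18 of 36 falling and 1 rising over all genes and when adjusted over the list alone. Serpinh1, the collagen chaperone HSP47 (-1.89 ± 0.15), Col14a1, a fibril-associated collagen (-2.03 ± 0.23), and the proteoglycan Lum (-1.48 ± 0.17) fell with Col15a1. The median was -0.60, with -0.67 on slide 1 and -0.55 on slide 2 (adjusted p = 5.23e-06, and adjusted p = 0.347 with an estimated correlation). Fibroblast markers moved in the same direction: of 15, 2 rose and 8 fell over all genes, and 3 rose and 9 fell when adjusted over the list alone. Thy1 fell (-0.97 ± 0.20) and the ferritin receptor Scara5 rose (0.75 ± 0.14). Their median was -0.51, with -0.49 on slide 1 and -0.59 on slide 2 (adjusted p = 0.0348, and adjusted p = 0.455 with an estimated correlation), and the call was lost without fasted replicate 1 (adjusted p = 0.0801). Of 28 cell cycle genes 1 rose and 10 fell over all genes, and 1 rose and 13 fell when adjusted over the list alone. Mcm5, a subunit of the DNA replication helicase (-1.40 ± 0.16), the mitotic kinase Aurka (-1.19 ± 0.17) and Tpx2, its activator (-2.59 ± 0.37, and -0.88 with normexp), fell, although Tpx2 was well above background on only 2 of the fasted arrays. The median was -0.68, with -0.80 on slide 1 and -0.50 on slide 2 (adjusted p = 0.000114, and adjusted p = 0.455 with an estimated correlation).

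Acute phase and inflammatory genes were higher: 7 of 23 rose and 1 fell over all genes and when adjusted over the list alone. Lcn2, the siderophore-binding protein lipocalin 2, rose 28.5-fold (4.84 ± 0.21, adjusted p = 5.88e-05), with 2 satiated arrays well above background, and by a log2 fold change of 3.34 with normexp background correction, and Osmr, the oncostatin M receptor, rose (0.97 ± 0.12). The median was 0.42, with 0.77 on slide 1 and 0.46 on slide 2 (adjusted p = 0.0145, and adjusted p = 0.347 with an estimated correlation), and slide 2 alone did not give the call (adjusted p = 0.0756). Interferon-induced genes were lower, with 2 of 26 rising and 6 falling over all genes, and 2 rising and 8 falling when adjusted over the list alone. Bst2, the antiviral protein tetherin (-1.02 ± 0.11), and the chemokine Cxcl9 (-1.99 ± 0.43) fell. The median was -0.31, with -0.20 on slide 1 and -0.46 on slide 2 (adjusted p = 0.0486, and adjusted p = 0.626 with an estimated correlation). This call was lost with the slide as a block (adjusted p = 0.0912), with the replicate number as a block (0.127), and without any array other than those of satiated replicate 1 and fasted replicate 1 (0.0509 to 0.106). It was also lost under quantile normalization with and without normexp, median centring, the stricter probe filter, every probe on its own, the deposited ratios, array weights and slide 1 alone (0.0544 to 0.377). Antigen presentation genes were not called (adjusted p = 0.574): 1 of 15 rose and 4 fell, also when adjusted over the list alone, among them the class II gene H2-Ab1 (-1.52 ± 0.29).

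Clock genes were not called as a list (adjusted p = 0.873, median 0.13), with 4 of 19 rising and 4 falling over all genes and when adjusted over the list alone. Dbp, a clock output transcription factor with a strong daily rhythm, fell 5.90-fold (-2.56 ± 0.32), as did Bhlhe40, a repressor within the clock (-0.67 ± 0.14). The hour at which hearts were taken is not given in the sources used here.

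The 10 largest increases among named genes with groups that did not overlap were led by Scgb3a1. This secretoglobin of airway epithelium rose 30.2-fold (4.92 ± 1.11, adjusted p = 0.0178), with values of 4.30, 4.36, -1.15 and 2.50 on fasted replicates 1 to 4 and of -2.84 to -2.08 in the satiated hearts. Dynlrb2, a dynein light chain, rose (3.70 ± 0.21), with 2 satiated arrays well above background. Tmem212, at least 5.54-fold higher (adjusted p = 0.000844), and Ccdc192, at least 3.74-fold higher (adjusted p = 0.00313), were not well above background on any satiated array. The acute phase genes Saa3 (4.18 ± 0.47) and Saa2 (3.99 ± 1.17), the protease inhibitor Serpina3n (3.89 ± 0.56), the apolipoprotein Apoc3 (3.90 ± 0.44) and the cytochrome P450 gene Cyp2b9 (3.74 ± 0.65) completed the 10 with Lcn2. Saa3 and Apoc3 were each well above background on 1 satiated array and Saa2 on 2. Saa2 was at 1.56, -4.13, -1.41 and -4.00 on fasted replicates 1 to 4, and its change was 2.80 without replicate 1. Saa2 (adjusted p = 0.0449) lost its call without any 1 of the satiated arrays or that of fasted replicate 3 (adjusted p = 0.0728 to 0.105), with normexp background correction (1.98, adjusted p = 0.103) and with dim probes kept (adjusted p = 0.0969). With normexp, whose offset shrinks the changes of dim genes, the 10 increases ran from 1.13 (Ccdc192) to 4.38 (Scgb3a1), and Tmem212 was at 1.41.

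The 10 largest decreases were led by Itgb6, the beta subunit of an integrin that activates TGF-beta (-5.57 ± 0.64, and -3.28 with normexp), and Prnd, which encodes the prion-like protein doppel (-5.47 ± 0.56, and -3.10 with normexp). Itgb6 was well above background on 2 fasted arrays and Prnd on 1. Rtn4r, the Nogo receptor, was at least 6.28-fold lower (adjusted p = 0.000243), Lrat, which esterifies retinol, at least 3.06-fold (adjusted p = 0.00182), Lctl at least 2.98-fold (adjusted p = 0.00991) and the lectin gene Cd209e at least 2.47-fold (adjusted p = 0.0184), and none of these was well above background on a fasted array. Car3, a carbonic anhydrase abundant in muscle and fat, fell (-3.67 ± 0.48), as did Aplnr, the apelin receptor (-3.23 ± 0.25), the carboxylesterase gene Ces2e (-3.32 ± 0.27) and the galactosyltransferase gene B3galt2 (-3.28 ± 0.57), the last 2 well above background on 2 fasted arrays each. The change of Car3 was -2.4 on slide 1 and -4.9 on slide 2. The calls of Lctl (adjusted p = 0.111) and Cd209e (adjusted p = 0.163) were lost with normexp background correction, and that of Cd209e also without fasted replicate 1 or satiated replicate 3 (adjusted p = 0.0504). With normexp the 10 decreases ran from -3.47 (Car3) to -0.59 (Lrat), with Rtn4r at -1.42, Ces2e at -1.17 and B3galt2 at -1.36, and the changes of the genes given as bounds, here and among the increases, were smaller than those bounds.

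Markers of other cells and neighbouring tissues that a dissected heart can hold were read as lists of the same kind, and 3 of 15 were called. Besides fibroblast markers, mesothelial markers, of the cell layer that covers the heart, were higher: 4 of 11 rose and none fell over all genes, and 5 rose when adjusted over the list alone. The keratins Krt18 (1.16 ± 0.13) and Krt8 (0.88 ± 0.19) and the uroplakin Upk1b (1.02 ± 0.21) were examples. Both keratins are also made by the lining cells of airways. On fasted replicates 1 to 4, Krt18 was at 1.2, 1.1, 1.5 and 1.3 and Krt8 at 0.05, 0.09, -0.37 and -0.39. Neither keratin was thus lower on replicate 3 than on replicate 4 of the same slide, whereas the airway secretory genes described below were. The median of the mesothelial markers was 0.59, with 0.51 on slide 1 and 0.59 on slide 2 (adjusted p = 0.00299, and adjusted p = 0.455 with an estimated correlation). Of 7 B cell markers 3 rose and none fell over all genes, and 5 rose when adjusted over the list alone. Vpreb3, which is expressed in the B lineage, rose (0.99 ± 0.18), as did Jchain, the joining chain of secreted antibody (3.32 ± 0.97, adjusted p = 0.0447), whose groups overlapped, whose change was 2.66 to 4.00 with 1 array left out, 2.13 with normexp, 4.76 on slide 1 and 1.88 on slide 2, and whose call was lost without any array other than those of satiated replicate 3 and fasted replicate 3 (adjusted p = 0.0721 to 0.1). The B cell median was 1, with 0.85 on slide 1 and 1.29 on slide 2 (adjusted p = 0.0123, and adjusted p = 0.499 with an estimated correlation), and slide 2 alone did not give the call (adjusted p = 0.0562).

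The other 12 cell-type lists were not called, with adjusted p from 0.0593 to 0.977. Of 6 neutrophil markers 3 rose over all genes, and 4 rose and 1 fell when adjusted over the list alone (median 1.28, adjusted p = 0.0593). Retnlg, a resistin-like protein of neutrophils, rose (3.64 ± 0.32, and 1.43 with normexp), with 1 satiated array well above background, and the list passed without fasted replicate 3 (adjusted p = 0.00417), satiated replicate 3 (adjusted p = 0.0392) or satiated replicate 4 (adjusted p = 0.0476) and on slide 1 alone (adjusted p = 0.00675). Of 17 macrophage markers 1 rose and 4 fell over all genes, and 2 rose and 4 fell when adjusted over the list alone (adjusted p = 0.356); Aif1 (-1.67 ± 0.32) and the fractalkine receptor Cx3cr1 (-2.43 ± 0.55, and -0.73 with normexp, well above background on 2 fasted arrays) fell. Of 5 lung markers 2 rose and 1 fell over all genes and when adjusted over the list alone (adjusted p = 0.912), among them Scgb1a1, the club cell secretory protein of airways (5.55 ± 1.66, adjusted p = 0.0483). Scgb1a1 was well above background on fasted replicates 1, 2 and 4 and on 2 satiated arrays, its change was 4.08 with normexp and 7.36 without fasted replicate 3, and its call was lost without any array other than that of fasted replicate 3 (adjusted p = 0.0767 to 0.112). Hopx, expressed in alveolar cells and heart muscle alike, fell (-0.84 ± 0.14).

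Skeletal muscle markers had a median of -1.19, with -2.59 on slide 1, where the list was called (adjusted p = 0.0221), and 0.19 on slide 2. Of 11 measured 1 fell over all genes and when adjusted over the list alone (adjusted p = 0.193), namely Casq1, the calsequestrin of skeletal muscle (-2.22 ± 0.41, and -1.10 with normexp, with 3 fasted arrays well above background). Atrial markers had a median of -0.32, with 3 of 13 falling over all genes and 4 when adjusted over the list alone (adjusted p = 0.163), Gja5 among them. Of 13 smooth muscle and pericyte markers 1 rose and 3 fell over all genes, and 2 rose and 3 fell when adjusted over the list alone (adjusted p = 0.977), with Smtn among those that fell (-1.28 ± 0.23). Of 8 nerve and Schwann cell markers 1 rose and 2 fell over all genes, and 2 rose and 3 fell when adjusted over the list alone (adjusted p = 0.53), with Gfra3 among those that fell (-1.01 ± 0.14). Among 7 erythroid markers 1 fell, and among 17 endothelial markers Icam2 fell (-0.86 ± 0.19), each alone in its list over all genes and when adjusted over the list alone (adjusted p = 0.785 and 0.977); the call of Icam2 was lost without satiated replicate 2 (adjusted p = 0.0526). Agt, angiotensinogen, was the 1 of 11 white adipocyte markers that rose (1.33 ± 0.21), and Pparg the 1 of 9 brown adipocyte markers (0.77 ± 0.14), the same when adjusted over the list alone (adjusted p = 0.975 and 0.83). Of 11 T cell and thymocyte markers Il7r rose (1.31 ± 0.29) and Thy1 fell, over all genes and when adjusted over the list alone (adjusted p = 0.929). Il7r was well above background on 3 fasted and 2 satiated arrays, had a change of 0.60 with normexp and lost its call without satiated replicate 2 (adjusted p = 0.0517). The signs of the median, the mean and the test differed for ketone body, adrenergic, antigen presentation, endothelial, T cell, white adipocyte, brown adipocyte and lung lists, and those of the median and of fry for de novo fatty acid synthesis.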

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

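The tests of the clock time of fasted replicate 3, of alveolar RNA and of a response shared by all 4 fasted mice were chosen only after their results were seen, and the spread that a ratio had to exceed was added to the tests of dim probes and of a stronger response after their values were known, as was the comparison of the clock genes with the satiated arrays. The lists of clock genes and of airway secretory genes were written after some of their members had been looked at.

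For 128 genes and 5 measures of array quality, each group of 4 hearts was searched for a value set apart from the other 3 by a gap, relative to the group's range, above Dixon's critical value. That value is passed by chance in about 1 of 20 groups, and it was passed in 13 of 266 (4.89%), all of them for genes and 6 of them on the array of fasted replicate 3. On that array Uvrag was at 3.59, against 2.70 to 2.76 in the other fasted hearts. Hmox1 was at 3.98, against 3.06 to 3.14. Mgst1 was at 5.93, against 5.14 to 5.20, and Grk5 at 2.36, against 1.71 to 1.75. Dhcr7 was at -0.65, against 0.05 to 0.15, and Tekt2 at -4.05, against -2.58 to -2.32. Among the other fasted hearts, Sdhd was at 6.26 in replicate 2, against 6.35 to 6.37, Acacb at 6.03 in replicate 1, against 5.97 in the rest (5.971 to 5.975), and Ifit2 at -0.91 in replicate 4, against -0.34 to -0.27. Among the satiated hearts, Apoc3 was at -4.78 in replicate 2, against -6.75 to -6.43, and Calr at 4.09 in the same heart, against 3.86 to 3.90. Lrat was at -3.73 in satiated replicate 3, against -3.32 to -3.24, and Nhp2 at 1.65 in satiated replicate 4, against 2.00 to 2.01.

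The array of fasted replicate 3 stood apart from the other fasted arrays across genes as well. Noise of dim probes is argued against as the whole cause. Among the brightest genes its deviation still spread 1.27 times as wide as that of the next array, with a resampling SD over genes of 0.0174. The resampling drew genes, which are not independent, so this SD may be too small. Among these genes the SD of the deviation was 0.414 on the array of fasted replicate 3. It was 0.292, 0.326 and 0.300 on those of fasted replicates 1, 2 and 4. A stronger response of the same kind could not be decided. The slope of the change on fasted replicate 3 against that on slide 1 was 1.0998 times that of fasted replicate 4, with a resampling SD of 0.0326. This was below the 1.2 that the test asked for and within that SD of the 1.1 under which a stronger response was to be excluded. Another clock time in that mouse could not be decided. Genes that peak with Nr1d1 lay 1.02 (log2) higher on the array of fasted replicate 3, relative to genes that peak opposite, than on the other fasted arrays, where the test asked for more than 1. Relative to the satiated arrays of the same slide, however, the median of the former genes minus that of the latter was -1.52 on it, against -2.17, -1.31 and -2.70 on fasted replicates 1, 2 and 4, so that it did not lie above all of them. A difference between individual mice in the depth of the fast was not tested.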

How the results depend on the processing

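The only test here chosen after the data were seen is the slide block without fasted replicate 3. Of the 4073 changed genes and unnamed probes, none was called in the opposite direction under any alternative by the probe that represents it or by the mean of its probes, while 36 other probes, of 35 genes, were called opposite to the representative probe with every probe on its own. The share of higher calls stayed between 46.0% and 51.1% wherever more than 1 gene passed. The count of changed genes moved to 7177 with the slide as a block, to 7505 when that block was used without fasted replicate 3, to 6486 with the replicate number as a block (which kept 3967 of the 4073), to 2225 with no filter on dim probes, to 1883 on slide 1 alone, to 1 on slide 2 alone, which was also the 1 gene changed at least 2-fold there, and to 1564 at an adjusted p under 0.01. The count at 2-fold moved from 1490 to 778 with normexp, to 768 with normexp and quantile normalization and to 949 at an adjusted p under 0.01. Fewer arrays and the stricter threshold lower counts by construction. Keeping dim probes raised the number tested to 32701, and the normexp offset shrinks the changes of dim genes. Both blocks take differences between the slides out of the residual spread. How much each of these moved the counts was not tested. Leaving out 1 array gave 2495 (without satiated replicate 4) to 3690 changed genes (without fasted replicate 3), with 2520 without satiated replicate 2, 1236 to 1591 at 2-fold, 19 to 23 called lists and a lowest correlation between replicates of 0.9708 to 0.9768. An adjusted p under 0.01 kept 13 of the 21 lists. An estimated correlation in camera left 0 called, with 6 at an unadjusted p under 0.05, and fry called 24. Over 27 alternatives the interferon list kept its call in 8, ATF4 in 18, proteasome and endoplasmic reticulum chaperones in 20 each and the other called lists in 24 to 26. Of the lists not called, the respiratory chain was called in 15 of 27, neutrophil markers in 11 of 26, citric acid cycle, heat shock and fatty acid uptake lists in 7 each and skeletal muscle, atrial and nerve markers in 1 each. Besides the interferon and chaperone lists, which lost their calls, and the respiratory chain, which gained one, the replicate block changed no list's call. Of 125 called genes named in the text, all but 20 kept their calls without any 1 array. The 20, all with an adjusted p of 0.0155 or more, were Saa2, Cd209e, Eci2, Acadl, Pdk4, Sdhd, Rora, Dcn, Ifit2, Cd74, Ms4a1, Jchain, S100a8, S100a9, Napsa, Scgb1a1, Myl7, Icam2, Il7r and Iqcg. Of the same 125, the filter-free setting lost 17, slide 1 alone 33, slide 2 alone 125, the stricter threshold 31, normexp with quantile normalization 7, quantile normalization and normexp 4 each, median centring and the deposited ratios 3 each, the added setting 2 and the mean of probes 1. The slide block, every probe on its own, array weights and the trended prior lost 0, as did the stricter filter among the 101 it kept. Under the replicate block Jchain (adjusted p = 0.0912) and S100a9 (adjusted p = 0.0684) lost their calls and Atp5g1 (adjusted p = 0.0451) and Tekt2 gained one each; for genes named here it changed no other call. With the mean of probes the changes of Aplnr (-1.94), Gja5 (-0.84), Cyp51 (-0.67) and Cyp2b13 (2.17) were smaller and that of Apln (-4.08) larger. Signal over background limits the dim genes, more on slide 2, where 54.4% to 55.6% of probes were well above background, than on slide 1, with 66.7% to 68.9%.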

Other observations

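Tests of alveolar RNA and of a response shared by all 4 fasted mice were chosen only after the result was seen, as were the list of airway secretory genes and the single genes described first. Apln, which encodes the ligand of Aplnr, was lower in the fasted hearts (log2 fold change -2.87 ± 0.25, SE, 4 hearts per group, limma adjusted p = 0.000533), in the same direction as its receptor. Tfrc, the transferrin receptor, fell (-3.04 ± 0.41, adjusted p = 0.00248), while Ftl1, the ferritin light chain (0.56 ± 0.12, adjusted p = 0.0121), and Hamp2, a hepcidin (1.98 ± 0.30, adjusted p = 0.00351), rose. Tfrc changed by -2.39 with normexp, and Hamp2 by 1.3 on slide 1 and 2.7 on slide 2. Beside Cyp2b9, its relatives Cyp2b10 (3.51 ± 0.71, adjusted p = 0.0114) and Cyp2b13 (3.59 ± 0.64, adjusted p = 0.00719) rose, with 2 and 3 satiated arrays well above background and values of 1.63 and 2.06 with normexp background correction, and whether probes of this gene family cross-hybridise was not tested. Marco, a scavenger receptor (3.58 ± 0.64, adjusted p = 0.00744), Chil3 (3 ± 0.31, adjusted p = 0.000994) and Clec4d (3.13 ± 0.29, adjusted p = 0.000683, with 3 satiated arrays well above background) rose as well, by 2.77, 2.04 and 2.07 with normexp.

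Of 20 motile cilia genes, all 4 fasted arrays lay above all 4 satiated arrays for 7, several of them not well above background on most arrays, and below for 3, Mlf1 (-0.67 ± 0.12, adjusted p = 0.00846), Iqcg (-0.47 ± 0.10, adjusted p = 0.016) and Tekt2 (-0.94 ± 0.40, adjusted p = 0.136); these were picked out after their values were seen. Scgb1a1 was at 3.03, 3.53, -4.56 and 1.53 on fasted replicates 1 to 4, against -6.21 to -3.63 in the satiated hearts. In satiated hearts, 4 to 6 of 11 airway secretory genes, 9 to 12 of 20 motile cilia genes, 5 to 13 of 18 epithelial junction genes and 9 to 13 of 15 cartilage genes were well above background.

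Airway secretory genes formed the first pattern examined. The median excess of 11 such genes over the satiated arrays of the same slide was 6.42, 6.49, -0.13 and 4.83 (log2) on fasted replicates 1 to 4. Only 4 to 6 of the 11 were well above background in satiated hearts. These sizes therefore depend on the lowest measurable values, which were higher on slide 2. Alveolar lung tissue as a source could not be decided, since its test was chosen after the result was seen. Sftpc, among the most abundant alveolar transcripts, was well above background on 1 of the 3 arrays concerned. The 4 measured alveolar genes had a median excess of -0.191, -0.056, 0.335 and -0.064 on fasted replicates 1 to 4. Napsa, a lung marker, was at -2.47, -1.66, -3.24 and -1.93 on these replicates, against -3.83 to -3.41 in the satiated hearts. Sftpd, counted here among the airway secretory genes, was well above background on replicates 1, 2 and 4 only. RNA from airway tissue carried along at dissection may be a source, as a hypothesis that stays open: 20 motile cilia genes had medians of 0.95, 1.21, 0.12 and 0.42 and 18 epithelial junction genes 1.41, 1.37, 0.15 and 1.13 on the same arrays, the lowest of the 6 on replicates 1, 2 and 4 being 0.419, under the 0.5 that the test asked for. The marker lists kept genes well above background on at least 1 array, 20 of 28 and 18 of 25 here. Some, such as Capsl and Spint1, passed on fasted arrays only, which raises the fasted medians by construction. The excess passed 1 for 9, 12, 3 and 5 of the cilia genes on fasted replicates 1 to 4. On these arrays 17, 20, 10 and 10 of the 20 were well above background. The higher floor of slide 2 can thus hold down the median of 0.419 on replicate 4. Tekt1 was highest on replicate 3 (-0.84, against -2.51 to -1.90 on the other fasted arrays), and Dynlrb2 was at -0.85, -0.19, -0.77 and -1.05. Cartilage of the windpipe could not be decided: the medians over 15 genes were 0.413, -0.057 and -0.400 on replicates 1, 2 and 4, none over the 0.5 asked for, but most of these genes were well above background in satiated hearts too, which would hide a small share. A response shared by the hearts of all 4 fasted mice could not be decided either, since the secretory genes, with a median of -0.127 on replicate 3, had been chosen for this very pattern.

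The second pattern was the single call on slide 2 alone. No response to fasting in the mice of that slide is argued against, since 98.8% of the genes called on slide 1 alone changed in the same direction on slide 2. A wider spread between arrays could be part of it but stayed undecided: the median residual SD on slide 2 was 1.33 times that on slide 1 (0.201 against 0.151), between the marks of 1.1 and 1.5 set for the test. Fasted hearts had a median SD of 0.214 on slide 2 and 0.123 on slide 1, and satiated hearts 0.108 and 0.117.

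The 8 arrays can be divided into groups of 4 in 35 ways. For the number of changed genes 1 of the 35, the real one, gave as many as 4073. The highest of the others was 2915, from the division that follows the slides. Arrays of different slides are thus not exchangeable, and the 35 divisions cannot by themselves exclude chance. Within slides the blocked count was 7177. At 2-fold, 1 of 35 gave as many as 1490, against 1070 for the next, and the same limit applies. For the number of called lists, 3 of 35 gave at least 21, the highest of the others also being 21, so chance cannot be excluded for that number. With the slide as a block the 18 divisions that part each slide evenly are too few for a share under 0.05; 1 of them, the real one, gave 7177, and the highest of the others was 0. Among the 8 divisions that part all 4 same-numbered pairs, the others gave 0 changed genes against 4073.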
